A study of Danio rerio with 12 samples.

How the data were processed

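Gene expression was measured in whole zebrafish (Danio rerio) larvae of the AB wild-type line on 12 Affymetrix arrays that carry probe sets for zebrafish transcripts. Per the labels, embryos were freed from the chorion with Proteinase K and injected with 5-HT (serotonin), with reserpine, which blocks the vesicular monoamine transporter, or with the vehicle. The sample titles place the injection of 5-HT and of reserpine at the zygote stage. The vehicle was a KCl solution with TRITC-dextran as a tracer, DMSO and ethanol. Larvae were collected at 2 or 4 days post fertilisation (dpf), and total RNA of a pool of 30 to 40 larvae was hybridised to each array. The 6 groups held 2 biological replicates each, per the labels, and the injected dose was not given in the sources used here. The control group of each day served as the reference for both treatments of that day.

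The deposited values were read as log2 expression values, printed with 2 decimals, for 73244 features, and they were used as deposited. The software and normalization with which the authors made them are not given in the sources used here. The array medians lay between 6.44 and 6.56, and no column of the table was left unused. The precision of every comparison is limited by the number of arrays, 2 per group.

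Features were named from the platform annotation supplied with the data, updated through a RefSeq gene table. Of the probe sets, 20491 carried 1 gene symbol, 842 carried several and 51911 carried none, and no gene was named from a probe set with several. Of the 20491, 20013 matched the RefSeq table and 1 symbol was updated. Symbols of list genes were matched regardless of case. The 37561 unnamed features among those tested (64.6%) may include control features, which could not be told apart and were therefore kept in the counts of features.

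A feature was tested if at least 2 of the 12 arrays reached that array's 25th percentile, which left 58127 features. Of these, 20566 carried 1 or more gene symbols and are called named features below. limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided) was fitted to all 12 arrays with 6 group means, so that the comparisons shared 1 estimate of the spread with 6 residual degrees of freedom and 3.53 prior degrees of freedom. The median standard error of a difference between 2 groups was 0.20 on the log2 scale. Each treatment was compared with the control of its day and with the other treatment, the controls were compared between days, and the effect of each treatment was compared between days as an interaction. Adjusted p is the Benjamini-Hochberg value within a comparison, and a feature was called changed at an adjusted p under 0.05. Counts of genes used 1 feature per symbol, the one with the highest mean over all arrays, which gave 18407 genes.

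Gene lists for 34 cell types, tissues and pathways were written from general knowledge, with 13 to 60 measured members each. In total 1186 of the 1383 listed genes were on the array. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 204 tests of 34 lists in 6 treatment comparisons, and a list was called shifted at an adjusted p under 0.05. Camera with an estimated correlation and fry (its directional p) were run beside it. The same 34 lists were tested between the control groups of the 2 days, adjusted over these 34 tests, and this test was chosen after seeing the data. Camera compares the members of a list with all other genes, so its direction can differ from that of the list's median. Fold changes of comparisons that share controls were correlated across features, and 100 simulated sets of unchanged groups gave the correlation and covariance that shared controls bring alone, with all arrays treated as independent.

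The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, except where a choice is said to have been made after seeing the data. The rule named, for each treatment against its control and for the controls between days, up to 10 genes with the largest rise and 10 with the largest fall among those that passed and whose replicates did not overlap between groups. Clone-based and provisional names were left out. Places left empty went to the genes with the smallest unadjusted p, given as values that did not pass. The other comparisons had 5 in place of 10. The rule also named 10 genes of serotonin and catecholamine synthesis, transport and breakdown, and from each list in the text the 4 members with the smallest unadjusted p in the list's direction. The text gives a selection of the genes the rule names.

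The fit was tested on simulated data built on the arrays for 5-HT against control at 2 dpf. With 58127 features and known changes, 31 of 100 features changed 2-fold and 92 of 100 changed 4-fold were recovered, and 10 of 133 calls were false. The list test was tested for reserpine against control at 4 dpf, where a shift of 0.3 given to the pancreas list was called and 0 other lists were, adjusted over the 34 lists. Simulated genes varied independently of each other. The simulation therefore cannot show how often unmoved lists are called where genes vary together.

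Alternatives covered median centring, quantile normalization, no filter or a filter at the 50th percentile, the replicate number as a block, trend and robust moderation, array weights, only the 6 arrays of the same day, other thresholds, 1 feature per gene, and leaving out each array in turn. Where an array was left out of a group, the remaining array was assumed to vary like the other groups. A group that a comparison does not use enters it only through the shared estimate of the spread. Leaving out either replicate of such a group therefore gives the same count of features. Tests limited to named features, the medians of shifted lists without each array, correlations with the controls split or simulated with 1 array fewer or with an effect shared by replicate number, and a test of the replicate number were added after seeing the data. The genes the rule names from shifted lists were put through the same alternatives, also after seeing the data. For 1 array, the second reserpine replicate of 4 dpf, the description label gave 2 days while the title, source and age labels gave 4 days, and it was kept at 4 dpf.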

Results

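The 12 arrays covered whole larvae at 2 and 4 dpf after injection of vehicle, 5-HT or reserpine, with 2 replicates in each of 6 groups. The question named by the series title is how serotonin present before neurons form bears on later development. Arrays of the same group correlated at r = 0.975 to 0.988, arrays of the same age but another group at 0.959 to 0.990, and arrays of different ages at 0.934 to 0.966. Genes of the exocrine pancreas, which makes digestive enzymes, parted the ages on every array, with a list mean of 6.03 to 7.03 at 2 dpf and 10.17 to 10.46 at 4 dpf. The 4 dpf reserpine replicate 2, whose labels disagree on its age, had a pancreas list mean of 10.17 and correlated at 0.971 to 0.990 with the other 4 dpf arrays and at 0.935 to 0.965 with the 2 dpf arrays.

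The first principal component of the 58127 tested features held 45.9% of the variance and separated the ages. The second held 17.1%. It parted 5-HT from control arrays at both ages, in opposite directions, and did not hold the reserpine replicates of 2 dpf together. It placed both 2 dpf controls, 2 dpf reserpine replicate 2 and both 4 dpf 5-HT arrays on one side, between 32.9 and 51.0, and the other 7 arrays on the other side, between -45.4 and -11.8. The 2 dpf reserpine replicates therefore lay on opposite sides, at -38.6 and 32.9. The liver list also varied within a group, with a mean of 8.74 on 2 dpf control replicate 1 and 9.82 to 10.3 on the other 5 arrays of 2 dpf.

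**Figure D1:**
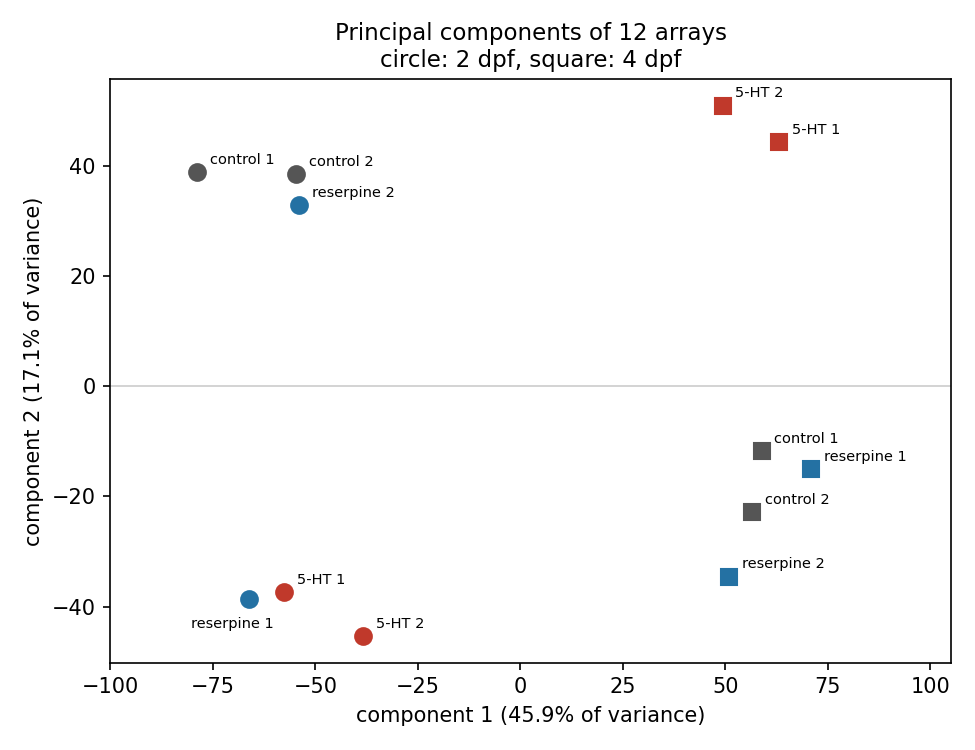
Scores of the 12 arrays on the first (x axis, 45.9% of variance) and second (y axis, 17.1%) principal components of all tested features. Circles stand for 2 dpf and squares for 4 dpf, and each point is marked with its injection and replicate number. The ages part on the x axis, and the 2 dpf reserpine replicates lie at -38.6 and 32.9 on the y axis.

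Control larvae were compared between 4 and 2 dpf to describe development without treatment. Camera called 19 of the 34 lists, 14 higher and 5 lower, and none held with an estimated correlation, where the adjusted p is given beside each median. The exocrine pancreas and enterocyte lists had the highest medians of the 34 lists. The exocrine pancreas list had a median log2 change of 4.17 (adjusted p = 0.122 with an estimated correlation), with 27 of 30 members higher. Among them were the trypsin gene prss59.1 (6.93, SE 0.78, adjusted p = 9.05e-04), the chymotrypsinogen gene ctrb.3 (6.4), the elastase genes ela2 (5.87, SE 0.19) and ela2l (6.19) and the amylase gene amy2a (6.12). Intestinal enterocyte genes had a median of 2.21 (adjusted p = 0.102 with an estimated correlation), and 22 of 33 rose while 1 fell. Among them slc15a1b, a peptide transporter, rose from 5.38 ± 0.08 to 11.32 ± 0.06 (SD, n = 2), a log2 change of 5.94, and fabp6, a bile acid binding protein, rose by 6.55.

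Photoreceptor genes had a median log2 change of 1.18 over 50 members (adjusted p = 0.256 with an estimated correlation), of which 30 rose and 1 fell. The retinoid carrier gene rbp3 rose by 2.21 (SE 0.23, adjusted p = 6.11e-04) and the rod transducin gene gnat1 by 1.98 (SE 0.27). Myeloid genes had a median of 0.52 (adjusted p = 0.211 with an estimated correlation), with 6 of 39 higher, including the macrophage gene mpeg1.2 (3.2), and interferon genes a median of 0.65 (0.365), with 7 of 31 higher, including irf1b (3.71) and stat2 (1.77). Among liver secretory genes ttr, which carries thyroid hormone, was higher by 4.29. The liver median was 0.65 (adjusted p = 0.630 with an estimated correlation), -0.09 without 2 dpf control replicate 1, where the call was lost (adjusted p = 0.874), and 1.45 without 2 dpf control replicate 2. The circadian list had a median of 0.31 (adjusted p = 0.651 with an estimated correlation), with 12 members higher and 2 lower, and its repressor gene nr1d1 rose by 4.41 (SE 0.32). That median was 0.60 without replicate 1 and 0.04 without replicate 2 of the 2 dpf controls, and 0.05 without replicate 1 and 0.75 without replicate 2 of the 4 dpf controls, with the list called each time.

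The cell cycle list had a median of -0.47 (adjusted p = 0.305 with an estimated correlation), with 16 of 58 lower, among them fen1 (-0.90) and gins1 (-0.87), both of DNA replication. Neural progenitor genes had a median of -0.50 (adjusted p = 0.211 with an estimated correlation), with 10 of 25 lower and 1 higher, including the proneural gene neurog1 (-1.35, SE 0.21, adjusted p = 0.0054) and the radial glia gene fabp7a (-0.85). Heat shock and unfolded protein response genes had a median of -0.50 (0.305), with 11 of 46 lower, including manf (-1.28). Pigment genes had a median of -0.46 (adjusted p = 0.452 with an estimated correlation), with 12 of 33 lower and 3 higher, and lost their call without 2 dpf control replicate 2 (median -0.295, adjusted p = 0.0797). The pteridine synthesis gene gch2 fell from 11.96 ± 0.06 to 9.57 ± 0.06 (SD, n = 2), a change of -2.39. The troponin gene tnnt2c fell by 1.98 and the hatching enzyme gene he1.1 by 2.97 (SE 0.71, adjusted p = 0.0284). The he1.1 call was lost without 2 dpf control replicate 1 (adjusted p = 0.173), 4 dpf control replicate 1 (0.163) or 4 dpf control replicate 2 (0.0712). Leaving out 4 dpf control replicate 2 also ended the calls of fen1 (0.0606), gins1 (0.0673) and fabp7a (0.0639), leaving out 2 dpf control replicate 1 those of fen1 (0.0624) and gins1 (0.0526), and leaving out 4 dpf control replicate 1 that of fen1 (0.0580).

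Of the serotonin genes, ddc, which makes serotonin and dopamine from their precursors, rose by 1.77 (adjusted p = 0.0063), the transporter gene slc6a4b by 0.93 (0.0093), the degrading enzyme gene mao by 0.85 (0.0105) and the receptor gene htr2ab by 0.52 (0.0298). The serotonin list had a median of 0.08 over 33 members (adjusted p = 0.256 with an estimated correlation), 4 of them higher over all features tested and 5 adjusted over the list alone. Without 4 dpf control replicate 1 none of the 4 genes passed (ddc 0.0562, slc6a4b 0.0772, mao 0.0878, htr2ab 0.130). The slc6a4b call was also lost without 2 dpf control replicate 1 (0.0695), and the htr2ab call without 2 dpf control replicate 1 (0.130), 2 dpf control replicate 2 (0.0689) or 4 dpf control replicate 2 (0.170). The serotonin list lost its call without 2 dpf control replicate 1 (median 0.165, adjusted p = 0.0592), 2 dpf control replicate 2 (0.0544) or 4 dpf control replicate 1 (0.0716), and had a median of 0.125 without 4 dpf control replicate 2. The catecholamine list was not called, with a median of 0.14 (adjusted p = 0.336).

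In this comparison limma called 6578 of 58127 features, 3196 higher and 3382 lower, and 2866 of them differed at least 2-fold. They included 2847 genes, 1524 higher and 1323 lower, of which 823 rose and 220 fell at least 2-fold. Of the 34 lists, fry called 16. The 7 other lists camera called were stress axis, glucocorticoid-responsive, neuropeptide, transmission, xenobiotic, ion-transporting skin cell and red blood cell genes, which had adjusted p = 0.211 to 0.651 with an estimated correlation. Without 2 dpf control replicate 2 the transmission (adjusted p = 0.0745) and red blood cell calls (0.285) were lost. Of the 19 lists, 14 kept their call without any 1 array. Adjusted over the list alone, 27 pancreas members rose, 26 enterocyte members rose and 1 fell, 34 photoreceptor members rose and 1 fell, 10 myeloid, 8 interferon and 4 liver members rose, and 14 circadian members rose and 2 fell. Likewise 26 cell cycle and 20 heat shock members fell, 14 neural progenitor members fell and 1 rose, and 15 pigment members fell and 5 rose. The count of features was 1626 without 2 dpf control replicate 1, 1710 without 4 dpf control replicate 1 and 1457 without 4 dpf control replicate 2.

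**Figure D2:**
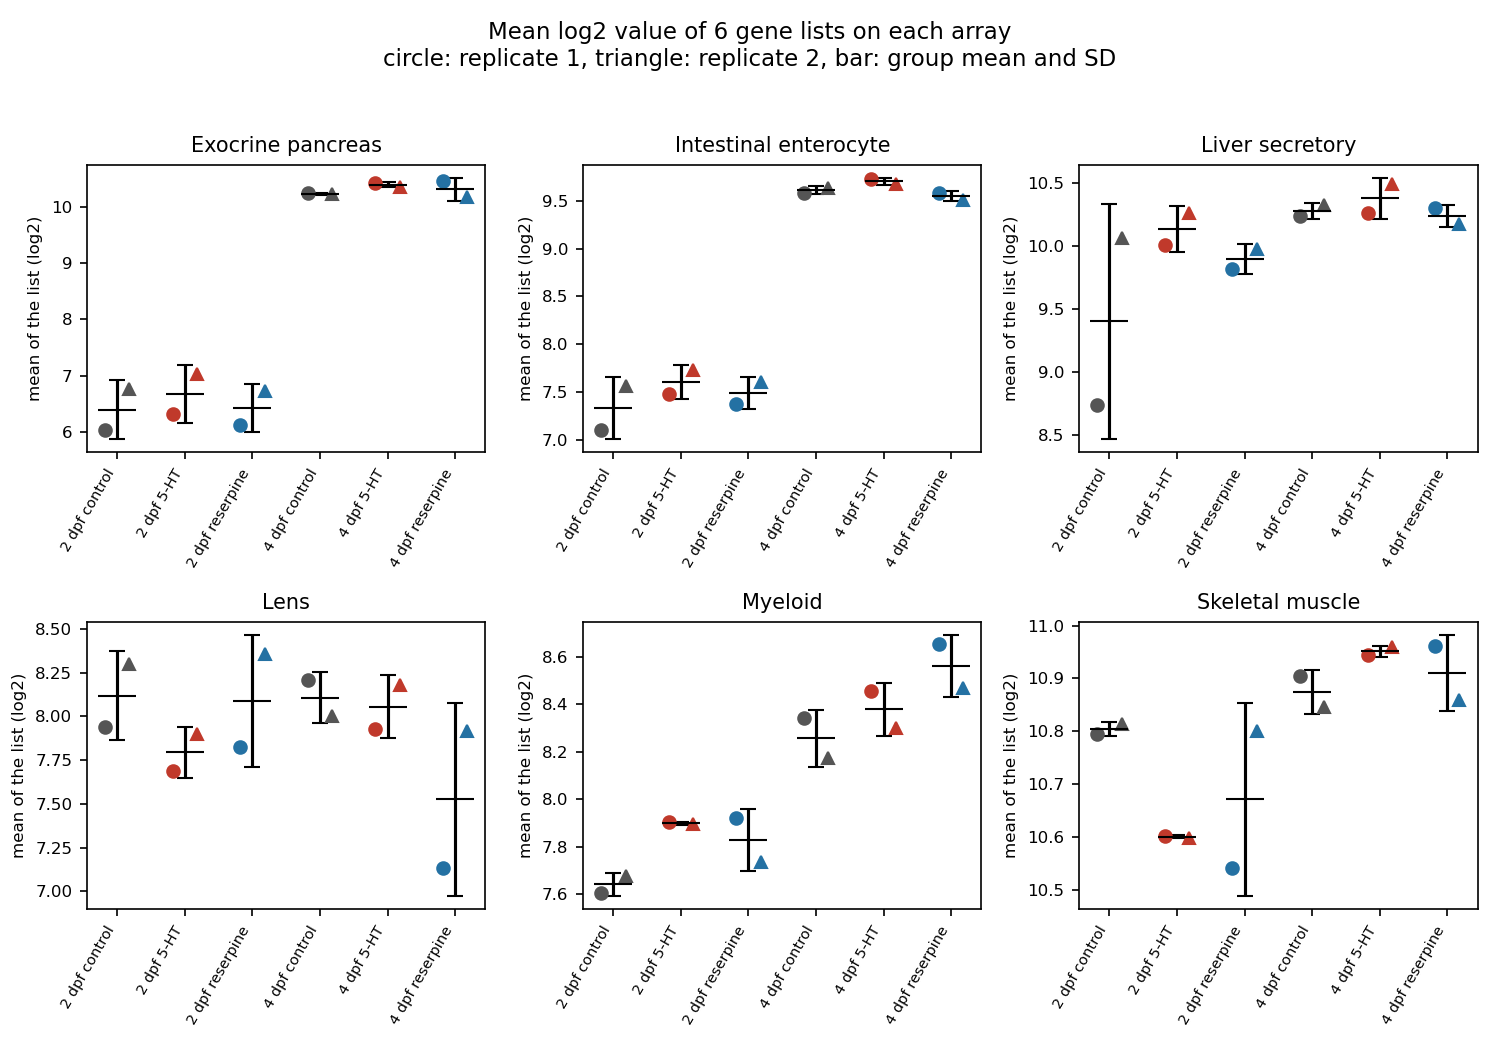
Mean log2 value (y axis) of 6 gene lists on each array by group (x axis), with circles for replicate 1, triangles for replicate 2 and bars for the group mean and SD. Pancreas lay between 6.03 and 7.03 at 2 dpf and between 10.17 and 10.46 at 4 dpf, liver was 8.74 on 2 dpf control replicate 1, and lens was 7.13 on 4 dpf reserpine replicate 1.

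For 5-HT against control at 2 dpf, the gene that passed was FCF1, a factor of ribosomal RNA processing, which fell by 1.5 (SE 0.14, adjusted p = 0.0382). Liver secretory genes had a median log2 change of 0.83, with 35 of 36 members above the control mean. Examples were the fibrinogen gene fga (0.87, SE 0.32) and the apolipoprotein gene apoa2 (0.79), neither of which passed. The controls disagreed on this list, with a mean of 8.74 on replicate 1 and 10.06 on replicate 2. The 5-HT arrays had 10.005 and 10.26, so control replicate 2 lay above 1 of them. Skeletal muscle genes lay lower, with a median of -0.18 and 46 of 60 below control, including the myosin binding gene mybpc2b (-0.94, SE 0.17), the troponin gene tnnt3a (-0.58) and the fast myosin gene myhz1.1 (-0.57). Lens genes had a median of -0.34, with 38 of 49 below control, and cell cycle genes a median of -0.13, with 48 of 58 below control, including the spindle checkpoint gene bub1bb (-0.70).

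Epidermal genes had a median of 0.15, with 37 of 43 above control, such as tp63 (0.62), and ion-transporting skin cell genes a median of 0.26, with 16 of 20 above control, such as their regulators foxi3a (0.52) and foxi3b (0.66). Myeloid genes had a median of 0.23 (mpeg1.2, 0.59), blood vessel genes 0.20 (esama, 0.55), xenobiotic and oxidative stress genes 0.22 (keap1b, 0.52) and enterocyte genes 0.18 (slc15a1b, 0.59). Pan-neuronal genes had a median of -0.17 with 21 of 31 below control, such as the neurofilament gene nefmb (-0.64). The serotonin transporter genes slc6a4a (0.48, SE 0.14, adjusted p = 0.158) and slc6a4b (0.49, adjusted p = 0.217) did not pass, nor did tph2, the neuronal enzyme of serotonin synthesis (-0.02). The serotonin list did not shift, with a median of -0.01, a mean of 0.01 and a test pointing up (adjusted p = 0.986), and the catecholamine list had a median of 0.02 (0.786).

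Camera called these 11 lists, 7 higher and 4 lower, from adjusted p = 4.38e-10 for liver, 1.40e-05 for muscle, 6.61e-04 for lens and 0.0018 for cell cycle to 0.0178 for pan-neuronal genes. None held with an estimated correlation or with fry: the smallest was adjusted p = 0.993 with an estimated correlation, where 0 lists had an unadjusted p under 0.05, and 0.809 with fry. Over all features tested 0 list members passed, and 1 did adjusted over the list alone, mybpc2b. The muscle call held without any 1 array. The muscle list mean was 10.80 and 10.81 on the 2 dpf controls and 10.60 on each 5-HT array. On 2 dpf reserpine replicate 1, which received no 5-HT, it was lower still at 10.54, and on replicate 2 it was 10.80. At 2 dpf the list thus parted the arrays as the second component did, which leaving out single arrays cannot test. The liver median was 0.09 without 2 dpf control replicate 1 (adjusted p = 0.712) and 1.52 without 2 dpf control replicate 2, where fga (1.49, adjusted p = 0.0337) and apoa2 (1.37, 0.0425) passed. The lens median was -0.18 without 2 dpf control replicate 2 (0.595), -0.23 without 2 dpf 5-HT replicate 1 (0.0786) and -0.55 without 2 dpf control replicate 1. The cell cycle median was -0.03 without 2 dpf control replicate 1 (0.216), -0.07 without 2 dpf 5-HT replicate 2 (0.104), -0.22 without 2 dpf 5-HT replicate 1 and -0.23 without 2 dpf control replicate 2. Without 2 dpf control replicate 1 the medians were 0.14 for epidermis (adjusted p = 0.135), 0.19 for myeloid (0.145), 0.14 for blood vessel (0.199), 0.09 for xenobiotic (0.580), 0.02 for enterocyte (0.887) and -0.17 for pan-neuronal genes (0.0958). Without 2 dpf 5-HT replicate 1 they were 0.10 for epidermis (0.271), 0.24 for ion cell (0.167), 0.18 for xenobiotic (0.0659) and -0.14 for pan-neuronal genes (0.0712), and 0.39 for enterocyte genes, which stayed past the threshold. Without 2 dpf 5-HT replicate 2 they were 0.10 for blood vessel (0.209) and 0.05 for enterocyte genes (0.326), and without 2 dpf control replicate 2 they were 0.44 for enterocyte and -0.26 for pan-neuronal genes. The number of lists called was 3 without 2 dpf control replicate 1 and 7 without 2 dpf 5-HT replicate 1.

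limma called 4 features at 2 dpf, FCF1 and 3 without a gene name, of which feature 13165794 rose by 2.31 (adjusted p = 0.0069) and features 13200308 and 13297952 fell by 2.28 and 1.4. These 3 were named after their values were seen. At an unadjusted p under 0.05 there were 8647 features, against 2906 by chance. Genes close to the threshold were the zinc finger gene zcchc14 (0.93, SE 0.16, adjusted p = 0.0637), the synaptotagmin gene syt9a (0.90), the kinase gene wnk4b (1.31), the cytochrome gene cyp3c3 (-1.24, adjusted p = 0.0601) and the respiratory chain gene ndufb4 (-1.19). The mitochondrial ribosome gene mrpl53 had 1.08 on the probe set used and the opposite sign on its other probe set. The count was 0 without 2 dpf control replicate 1, 2 dpf 5-HT replicate 1 or 2 dpf 5-HT replicate 2, and 208 without 2 dpf control replicate 2. It was 1215 without either 2 dpf reserpine replicate, 1 without any single 4 dpf array and 0 with only the 6 arrays of 2 dpf. The FCF1 change lay between -1.58 and -1.43 with any array left out. Its call was lost without 2 dpf control replicate 1 (adjusted p = 0.150), 2 dpf 5-HT replicate 1 (0.108) or 2 (0.337), either 4 dpf control (0.0915), either 4 dpf 5-HT array (0.0824) or either 4 dpf reserpine array (0.0626). It was also lost with only the arrays of 2 dpf (0.208). Without either 2 dpf reserpine replicate zcchc14 (0.0179), syt9a (0.0291), wnk4b (0.0081), cyp3c3 (0.0228), ndufb4 (0.0262), mrpl53 (0.0243), mybpc2b (0.0246) and foxi3b (0.0495) passed.

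For reserpine against control at 2 dpf, liver secretory genes had a median log2 change of 0.58, with 32 of 36 members above the control mean. Examples were apoa2 (0.75, SE 0.31) and the plasminogen gene plg (0.89). The liver list mean was 9.82 and 9.98 on the reserpine arrays, between the controls at 8.74 and 10.06. Genes of inhibitory and excitatory transmission had a median of -0.15, with 33 of 35 below control, among them the GABA synthesis gene gad2 (-0.34) and the GABA receptor gene gabra3 (-0.43). Skeletal muscle genes had a median of -0.09, with 47 of 60 below control, including the giant sarcomere genes neb (-0.67) and ttn.2 (-0.84), while heart muscle genes had a median of 0.08, with tnnc1a at 0.52 (SE 0.15) and the atrial peptide gene nppa at 0.46. Myeloid genes had a median of 0.13, with 33 of 39 above control, including the inflammatory cytokine gene il1b (1.07, SE 0.40).

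Camera called 10 lists, 7 higher and 3 lower. Besides liver (adjusted p = 8.48e-13), transmission and myeloid (0.0011), muscle (0.0017) and heart (0.0173), they were epidermis (median 0.06), xenobiotic and oxidative stress (0.06), enterocyte (0.07), pigment (0.08) and pan-neuronal genes (-0.12). None held with an estimated correlation or with fry, the smallest being adjusted p = 0.993 with an estimated correlation, where 0 lists had an unadjusted p under 0.05, and 0.809 with fry, and 0 members passed, over all features or adjusted over the list alone. Without 2 dpf control replicate 1 the liver median was -0.11 and the test turned to lower (adjusted p = 0.0096), and without 2 dpf control replicate 2 it was 1.28. Without 2 dpf reserpine replicate 1, which lay with the 5-HT arrays on the second component, the medians were 0.03 for transmission, -0.0025 for muscle and 0.04 for myeloid genes (adjusted p = 0.615, 0.892 and 0.411), and without replicate 2 they were -0.39, -0.25 and 0.20. Without 2 dpf control replicate 1 transmission had -0.07 (0.195), myeloid genes 0.14 (0.2) and heart -0.04 (0.968), muscle lost its call without 2 dpf control replicate 2 (0.293), and heart without 2 dpf reserpine replicate 2 (0.314). Each of the 5 lists named last lost its call without 2 dpf control replicate 1 (adjusted p from 0.140 for pan-neuronal to 0.962 for xenobiotic genes). Enterocyte aside, they also lost it without 2 dpf reserpine replicate 1, while enterocyte genes lost it without 2 dpf reserpine replicate 2, with a median of -0.13. Pigment and xenobiotic genes lost it without 2 dpf reserpine replicate 2 too. Pigment and enterocyte genes also lost it without either 2 dpf 5-HT array, and pan-neuronal genes without 2 dpf control replicate 2. The number of lists called was 6 without 2 dpf control replicate 1.

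limma called 0 features for reserpine at 2 dpf, with 2424 at an unadjusted p under 0.05 against 2906 by chance. Among genes the smallest p belonged to FCF1 (-0.86, SE 0.14, adjusted p = 0.998), followed on the higher side by the neuroendocrine gene scg5 (0.66, SE 0.18) and the glucagon receptor gene gcgra (0.69). The serotonin and catecholamine genes ddc (-0.46, SE 0.29), tph1b (-0.27), slc6a4b (0.30) and slc18a2 (0.14), the transporter that reserpine blocks, did not pass. The serotonin list had a median of -0.04 and a mean of -0.02 with a test pointing up (adjusted p = 0.912), and the catecholamine list had a median of -0.05 (0.540). Without 2 dpf reserpine replicate 2 the count of features was 97.

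For 5-HT against control at 4 dpf, no gene passed. The genes with the smallest p included the tropomyosin gene tpm1 (1.73, SE 0.34, adjusted p = 0.306) and the calmodulin gene calm3b (1.48, SE 0.30) on the higher side. On the lower side were wnk4b (-1.20, SE 0.27), the adhesion receptor gene adgrb2 (-0.95, SE 0.17, adjusted p = 0.256) and the G protein gene gng5 (-0.92). The other probe set of gng5 had the opposite sign. Neural progenitor genes had a median of 0.14, with 20 of 25 above control, such as the glial gene s100b (0.43, SE 0.19), sox19b (0.39) and the proneural gene ascl1a (0.29). The dopamine synthesis gene th was at 0.51 (SE 0.25, adjusted p = 0.630) and ddc at 0.36. The serotonin list had a median of -0.03, a mean of 0.02 and a test pointing down (adjusted p = 0.928), and the catecholamine list a median of 0.0025, a mean of 0.03 and a test pointing down (0.986).

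limma called 0 features, with 4943 at an unadjusted p under 0.05 against 2906 by chance, and the smallest adjusted p was 0.114. The neural progenitor list was the 1 list called (adjusted p = 0.0443), at adjusted p = 0.993 with an estimated correlation and with no call by fry, and 0 of its members passed over all features or adjusted over the list alone. It was lost without 7 of the 12 arrays: the 5 arrays 2 dpf control replicate 1 (adjusted p = 0.0576), 5-HT replicate 1 (0.0501) and 2 (0.0511) and reserpine replicate 1 (0.0648) and 2 (0.0632) of 2 dpf. The others were 4 dpf control replicate 1 (0.156) and 4 dpf 5-HT replicate 2 (0.226). The number of lists called was 8 without 4 dpf 5-HT replicate 2 and 4 without 4 dpf 5-HT replicate 1 or either 4 dpf control. The count of features was 372 without either 2 dpf reserpine replicate, where tpm1 (adjusted p = 0.0092), calm3b (0.0424), adgrb2 (0.0313) and wnk4b (0.0223) passed, and 32 with only the 6 arrays of 4 dpf.

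For reserpine against control at 4 dpf, genes of the lens lay lower, with a median log2 change of -0.59 and 46 of 49 members below control. They included the galectin-related lens gene grifin (-0.88, SE 0.27), the lens water channel gene mipb (-1.16, SE 0.42), lim2.1 (-0.80) and the crystallin gene cryba1b (-1.04). Inflammatory genes lay higher: myeloid genes had a median of 0.20, with 31 of 39 above control, such as the matrix protease gene mmp9 (1.3, SE 0.33) and il1b (1.29, SE 0.40). Interferon genes had a median of 0.15, with 26 of 31 above control, such as ifi44a1 (1.05, SE 0.67), and immediate early genes a median of 0.08 with 25 of 34 above control, such as fosl1a (1.63, SE 0.79). The acute phase gene crp3 stood at 1.19 (SE 0.27).

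None of these genes passed, and limma called 0 features, with 1004 at an unadjusted p under 0.05 against 2906 by chance. Camera called 8 lists, 5 higher and 3 lower, with adjusted p = 9.99e-37 for lens, 2.45e-12 for myeloid, 6.86e-05 for interferon and 1.10e-04 for immediate early genes. Cholesterol synthesis (median -0.10), skeletal muscle (0.04), cartilage and bone matrix (-0.09) and exocrine pancreas (0.07) were also called. None held with an estimated correlation or with fry, the smallest being adjusted p = 0.993 with an estimated correlation, where 2 lists had an unadjusted p under 0.05, and 0.809 with fry, and 0 members passed, over all features or adjusted over the list alone. All 8 lost the call or the sign of the median without 4 dpf reserpine replicate 1, where the lens list mean was 7.13 against 7.92 on replicate 2 and 8.21 and 8.01 on the controls. Without that array the medians were -0.21 for lens (adjusted p = 0.242), -0.04 for myeloid (4.52e-04), -0.15 for interferon (0.993), -0.06 for immediate early (0.373), -0.04 for cholesterol (0.993), 0.01 for muscle (0.223), -0.08 for cartilage (0.198) and -0.07 for pancreas genes (0.909). The test there pointed up, against the median, for myeloid, immediate early, cholesterol and pancreas genes. Without replicate 2 the lens median was -1.07, myeloid 0.36, interferon 0.38, immediate early 0.24, cholesterol -0.15 and pancreas 0.20, while muscle (0.08, 0.123) and cartilage (-0.04, 0.216) lost their call. Without 4 dpf control replicate 2 interferon had 0.05 (0.326) and immediate early genes 0.01 (0.256), and muscle (0.408), cartilage (0.243) and pancreas genes (0.107) lost their call. Without 4 dpf control replicate 1 myeloid had 0.34, interferon 0.33 and immediate early 0.19, and cholesterol (0.197), cartilage (0.0568) and pancreas genes (0.0593) lost their call. Cartilage also lost it without 2 dpf control replicate 1 (0.0604).

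The serotonin and catecholamine systems gave small values under reserpine at 4 dpf. The gene of the degrading enzyme mao was at -0.28 (SE 0.16), slc18a2 at 0.10 (SE 0.18), th at -0.04 and tph2 at 0.03, and a serotonin receptor subunit gene, HTR3B, at -0.50 (SE 0.18), each with an adjusted p of 1. The serotonin list had a median of -0.04 (adjusted p = 0.466) and the catecholamine list a median of -0.08 with 24 of 30 below control (0.158).

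The treatments, one that adds serotonin and one that empties its vesicles, were also compared directly. At 2 dpf ion-transporting skin cell genes lay higher in 5-HT than in reserpine larvae, with a median of 0.25 and 16 of 20 higher, such as ca15a (0.81, SE 0.22), and blood vessel genes had a median of 0.12, with the receptor gene kdr at 0.36. Lens genes had a median of -0.29 with 44 of 49 lower, cell cycle genes -0.11, muscle genes -0.05 and neural progenitor genes -0.06, with neurog1 at -0.62. At 4 dpf lens genes lay higher in 5-HT larvae, with a median of 0.52 (crygn1, 0.85, SE 0.27), cholesterol synthesis genes had 0.25 (acat2, 0.54), and myeloid genes -0.06 (mmp9, -1.17, SE 0.33).

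limma called 0 features at 2 dpf, with 3513 at an unadjusted p under 0.05, and 0 at 4 dpf, with 6270. The genes with the smallest p included the ribosomal gene mrps12 (0.73, SE 0.16) and the GABA receptor gene gabrr3a (-0.67) at 2 dpf and tpm1 (1.87, SE 0.34, adjusted p = 0.208) and adgrb2 (-0.98) at 4 dpf. Camera called 6 lists at 2 dpf, from adjusted p = 2.27e-08 for lens to 0.0153 for neural progenitors, and 3 at 4 dpf, with 6.88e-07 for lens, 0.0122 for cholesterol and 0.0346 for myeloid genes. None held, the smallest being adjusted p = 0.993 with an estimated correlation, where 1 list at 2 dpf and 0 at 4 dpf had an unadjusted p under 0.05, and 0.809 with fry, and 0 members passed, over all features or adjusted over the list alone. At 2 dpf the lens median was -0.005 without 2 dpf reserpine replicate 2 (adjusted p = 0.0675) and -0.47 without replicate 1, and the ion cell median was 0.19 without 2 dpf 5-HT replicate 1 (0.0659). At 4 dpf the lens median was 0.10 without 4 dpf reserpine replicate 1 (0.777, with a test pointing down) and 0.93 without replicate 2. Cholesterol was lost without 4 dpf reserpine replicate 1 (0.373) or 4 dpf 5-HT replicate 2 (0.0511). The myeloid median was 0.19 without 4 dpf reserpine replicate 1 (0.393), -0.03 without 4 dpf 5-HT replicate 2 (0.253) and -0.06 without 2 dpf control replicate 1 (0.0692). At 2 dpf cell cycle lost its call without 2 dpf 5-HT replicate 2 (0.172) or 2 dpf reserpine replicate 1 (0.247), and muscle without 2 dpf 5-HT replicate 1 (0.0501) or 2 dpf reserpine replicate 2 (0.788). Blood vessels lost it without 2 dpf 5-HT replicate 2 (0.347) or 2 dpf reserpine replicate 1 (0.0607), and neural progenitors without 2 dpf 5-HT replicate 1 (0.0501) or 2 (0.0850) or 2 dpf reserpine replicate 1 (0.0998) or 2 (0.0757). The number of lists called at 4 dpf was 1 without 4 dpf reserpine replicate 1, 8 without replicate 2, 7 without 4 dpf 5-HT replicate 1 and 5 without replicate 2. The count of features was 191 without 2 dpf reserpine replicate 1 at 2 dpf, and at 4 dpf 421 without either 2 dpf reserpine replicate, where tpm1 (0.0091) and adgrb2 (0.0290) passed, and 23 with only the 6 arrays of 4 dpf.

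The effects of the treatments were set against each other across the 58127 features, which are not independent replicates. At 2 dpf the effects of 5-HT and reserpine correlated at r = 0.697 (rho = 0.642) with 73.0% of features of the same sign, where the shared controls alone gave a simulated r of 0.50 with arrays treated as independent, and the covariance was 0.0763 against a simulated 0.0311. At 4 dpf r was 0.202 (rho = 0.167), against the same simulated r, and the covariance was 0.0144 against 0.0311. The simulation drew features independently of each other, with 1 spread per feature for both days. It therefore does not allow for a factor that moves many features together, or for a spread that differs between days. With 1 control array for 5-HT and the other for reserpine, which was chosen after seeing the data, r was 0.248 or 0.163 at 2 dpf (covariance 0.0353 or 0.0271) and -0.04 or -0.15 at 4 dpf (-0.0039 or -0.0154), according to which control served which treatment. Simulated groups without change gave a split r of -0.0879 at 2 dpf and -0.0984 at 4 dpf where arrays of the same replicate number share an effect, and a covariance with shared controls of 0.0241 and 0.0233. The shared-control value at 2 dpf was 0.380 without 2 dpf reserpine replicate 1, where the simulated r was 0.408. The 4 dpf value was 0.456 without 4 dpf control replicate 1 and 0.325 without 4 dpf control replicate 2, where the simulated r was 0.667, and -0.03 without 4 dpf reserpine replicate 1, where it was 0.408. Between days the effects of reserpine correlated at r = 0.0714 (rho = 0.0542), which became 0.172 without 4 dpf reserpine replicate 1 and -0.05 without 4 dpf reserpine replicate 2, and those of 5-HT at r = -0.453 (rho = -0.336).

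The effect of 5-HT differed in direction between the days for a set of genes. The muscle gene tpm1 was at -1.49 (SE 0.34) at 2 dpf and 1.73 (SE 0.34) at 4 dpf, a difference of 3.22 (SE 0.49, adjusted p = 0.0208). The gene calm3b differed by 2.83, the zinc finger gene znfl1g by 3.30, FCF1 by 2.13 (SE 0.20, adjusted p = 0.0160) and ndufb4 by 2.04. In the other direction wnk4b was at 1.31 (SE 0.27) at 2 dpf and -1.20 at 4 dpf, a difference of -2.50 (adjusted p = 0.0211), and the forkhead gene foxj2 (-2.49), the Wnt coactivator gene pygo2 (-2.49), wipf2b (-2.37) and lrtm2a (-2.21) followed it. Each of these 10 genes lost its call without 2 dpf control replicate 1, 2 dpf 5-HT replicate 2, either 4 dpf control or either 4 dpf 5-HT array. The highest adjusted p was 0.104 for FCF1 and 0.159 for znfl1g, both without 4 dpf control replicate 2. All but FCF1 also lost it without 2 dpf control replicate 2, tpm1, znfl1g, foxj2, pygo2, wipf2b and lrtm2a without 2 dpf 5-HT replicate 1, and znfl1g, foxj2 and pygo2 without either 4 dpf reserpine array (0.0519, 0.0538 and 0.0615). The features with a higher effect at 4 dpf had a median log2 change of -1.23 at 2 dpf and 0.95 at 4 dpf, and those with a lower effect 0.85 and -0.71.

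limma called 1253 features for this difference, 824 with a higher and 429 with a lower effect at 4 dpf, and 99.5% of them had effects of opposite sign at the 2 ages. They were selected for a difference between these effects, and over all features 38.3% had effects of the same sign. Of these, 1101 (87.9%) had no gene name, against 64.6% of the features tested, and the 152 named features gave 112 genes, 19 higher and 93 lower, of which 1 passed when adjusted over 18407 genes. Over the called features the 2 dpf reserpine arrays, which are not in the contrast, lay at 81.0% (replicate 1) and 18.4% (replicate 2) of the way from the control to the 5-HT mean of 2 dpf. The count was 0 without 2 dpf control replicate 1, 2 dpf 5-HT replicate 2, 4 dpf control replicate 2 or either 4 dpf 5-HT array, and 3 without 4 dpf control replicate 1. It was 236 without 2 dpf control replicate 2, 325 without 2 dpf 5-HT replicate 1 and 2458 without either 2 dpf reserpine array. For reserpine limma called 0 features that differed between the days, with 1430 at an unadjusted p under 0.05, and among genes FCF1 had the smallest p (0.91, SE 0.20, adjusted p of 1.00).

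**Figure D3:**
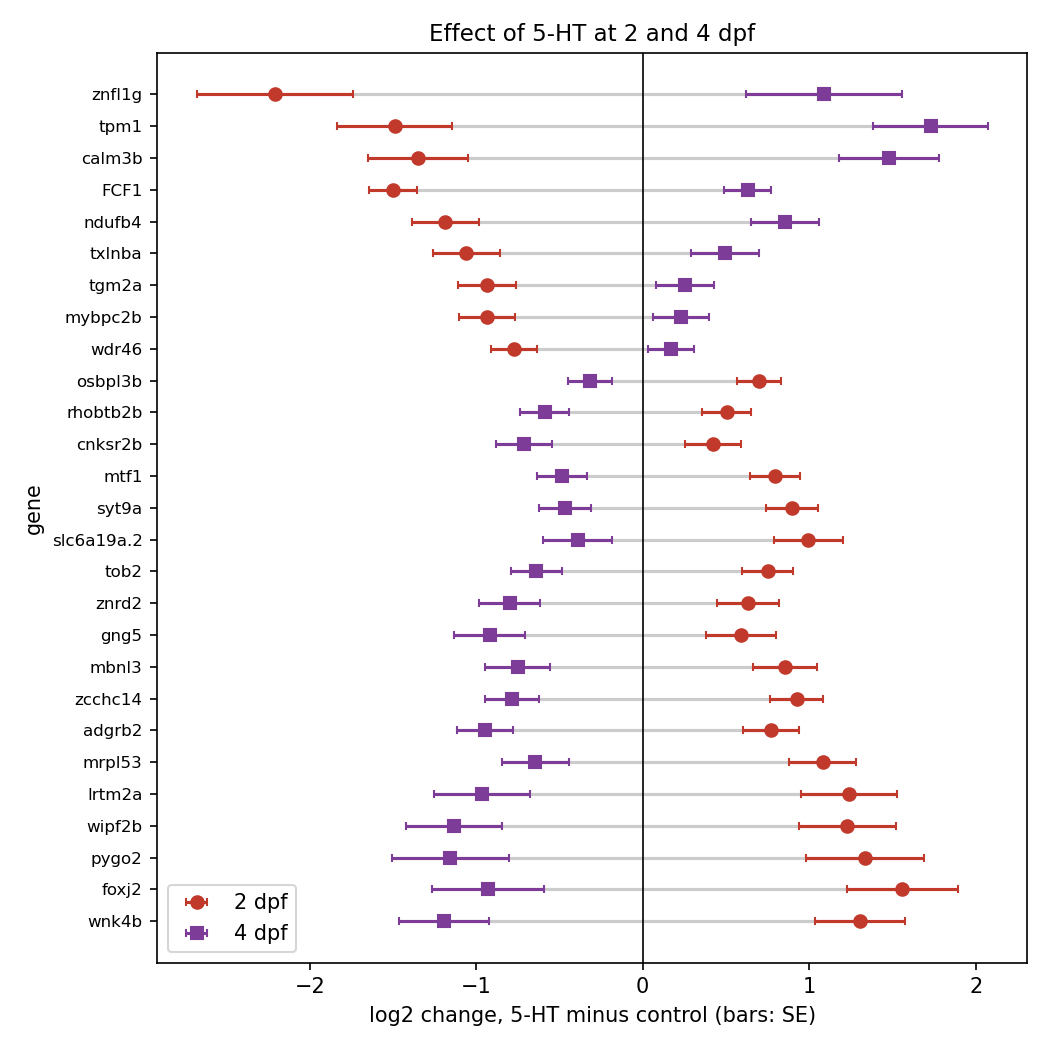
Log2 change of 5-HT against control (x axis, bars give the SE) at 2 dpf (red circles) and 4 dpf (purple squares) for 27 genes (y axis). They are the genes of the naming rule among the 112 called for a difference in effect between the days, and were thus selected for this difference. The effects lie on opposite sides of 0 for each of them, as for tpm1 at -1.49 and 1.73.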

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

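The tests of a difference between arrays, of the injection of 5-HT and of a stage shift of the whole larva were chosen only after the result was seen, and the tests of stage by correlation were written before. The effect of 5-HT differed between 2 and 4 dpf by a test of the difference itself in 1253 features, and 27 genes of the naming rule were among them. The differences (4 dpf minus 2 dpf, log2) were positive for the zinc finger gene znfl1g (3.30), the tropomyosin gene tpm1 (3.22), the calmodulin gene calm3b (2.83), FCF1 (2.13), the respiratory chain gene ndufb4 (2.04), txlnba (1.56), the transglutaminase gene tgm2a (1.19), the fast muscle gene mybpc2b (1.17) and wdr46 (0.95). They were negative for the kinase gene wnk4b (-2.50), the forkhead gene foxj2 (-2.49), the Wnt coactivator gene pygo2 (-2.49), wipf2b (-2.37), lrtm2a (-2.21), the mitochondrial ribosome gene mrpl53 (-1.73), the adhesion receptor gene adgrb2 (-1.72), zcchc14 (-1.71), the splicing regulator gene mbnl3 (-1.61), the G protein gene gng5 (-1.51), znrd2 (-1.43), tob2 (-1.39), the amino acid transporter gene slc6a19a.2 (-1.39), syt9a (-1.36), the metal response gene mtf1 (-1.28), cnksr2b (-1.14), rhobtb2b (-1.10) and osbpl3b (-1.02). Adjusted p (limma) lay between 0.0160 (FCF1) and 0.0456 (slc6a19a.2), with 2 arrays per group. The 1253 features held 112 genes, and 1 gene passed when adjusted over 18407 genes. Over the 1253 features the 2 dpf reserpine arrays, which received no 5-HT, lay 81.0% (replicate 1) and 18.4% (replicate 2) of the way from control to 5-HT. The effects ran in opposite directions at 2 and 4 dpf in 99.5% of the 1253 features, which were selected for such a difference (38.3% of all features had the same sign).

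A shift in developmental stage of the whole larva as the whole cause was not decided. The change with age in reserpine larvae correlated with the contrast at r = -0.774 (-0.253 over all features), past the bound written before in favour of a stage shift. It was -0.314 or -0.885 according to which 2 dpf reserpine replicate was the younger sample. The higher of these values met neither bound written for that test. The 1253 features, selected for the contrast, moved 92.8% of their control age change forward at 2 dpf and 73.6% back at 4 dpf. With features chosen in 1 replicate number and measured in the other, the sums were 131% and 117%. The same control arrays stand in the effects and in the age change, which can raise these sums, and no value for unchanged features was simulated. The sums therefore cannot show that these features passed 100% of their age change. The 6578 features called between control ages, 899 of them among the 1253, moved 46.4%. The pancreas, enterocyte and photoreceptor lists moved 3.95%, 2.90% and 6.49% in sum (at most 17.0% without any 1 array). By day they moved 7.22%, 6.49% and 10.7% forward at 2 dpf. At 4 dpf they moved by -3.27%, -3.59% and -4.18% back, which is slightly forward, unlike the 1253 features. These list values argue against a shift of 100% in sum for steadily rising genes, but not against a smaller one. A difference between arrays that is not treatment may be part of the pattern. Over the 1253 features the difference between the 2 dpf reserpine replicates, which are not in the contrast, correlated with the contrast at r = 0.907. Over all features r was 0.486, and features are not independent replicates. The injection of 5-HT, the biological explanation the design gives, stays open: the 2 dpf reserpine replicates lay 62.6% of the way from control to 5-HT apart, past the bound of 50 written against it, but that bound was wrong by design because reserpine larvae received no 5-HT. It and the split of the arrays on the second component cannot be told apart, since both replicates of the control and of the 5-HT group at each age lie on 1 side of it, and an exchange of control and 5-HT labels at 1 age, which would turn the sign of every 5-HT effect there, was not excluded by any value.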

How the results depend on the processing

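The tests limited to named features, the values of list members under the alternatives, the split of the controls with its simulation and the check of replicate numbers were chosen only after the result was seen. The number of arrays, 2 per group, limits the precision, and signal over background could not be judged because background features could not be told apart. The counts of 0 features for reserpine at 4 dpf and for the reserpine difference between days were 0 under every alternative (limma, 1004 and 1430 at an unadjusted p under 0.05), and the correlation of 5-HT effects between days (-0.453) stayed negative, from -0.532 to -0.368. Of 6671 values of named genes under alternatives, 6391 kept their side of the threshold, 41 of these with a changed sign and no call either way, 216 lost and 64 gained a call, and 0 called values reversed.

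For 5-HT at 2 dpf the 4 features became 13 with median centring, 8 with quantile normalization, 19 with the filter at the 50th percentile, 1 with array weights, 0 with only the arrays of that day, 860 at adjusted p under 0.1, and 1 with 1 feature per named gene or with named features adjusted alone or fitted alone, where fewer features were tested. Without single arrays it ranged from 0 to 1215. With the replicate number as a block, overall or within day, 1 feature passed. The other counts of 0 became 175 with array weights and 32 with only the arrays of that day for 5-HT at 4 dpf, 23 with only the arrays of that day for 5-HT against reserpine at 4 dpf, and 1 at adjusted p under 0.1 for 5-HT against reserpine at 2 dpf. Without single arrays they ranged from 0 to 97 for reserpine at 2 dpf, 0 to 372 for 5-HT at 4 dpf, and 0 to 191 and 0 to 421 for 5-HT against reserpine at 2 and 4 dpf. For control age the 6578 features became 10559 at adjusted p under 0.1 and 3798 with named features adjusted alone, and ranged from 1457 to 7202 without single arrays. For the 5-HT difference between days the 1253 features became 2325 with array weights, 2863 at adjusted p under 0.1, 1 with 1 feature per named gene or with named features adjusted alone and 17 with them fitted alone, and ranged from 0 to 2458 without single arrays. The cause was not tested.

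Every list call in the 6 treatment comparisons became 0 with camera at an estimated correlation and 0 with fry, neither of which uses the preset correlation. The 1 list of 5-HT at 4 dpf became 0 with quantile normalization, 0 with the filter at the 50th percentile, 0 with only the arrays of that day and 3 with the replicate block within day, and the 3 lists of 5-HT against reserpine at 4 dpf became 5 with that block. Without single arrays the numbers of lists ranged from 3 to 14 for 5-HT and 6 to 13 for reserpine at 2 dpf, 0 to 8 for 5-HT and 6 to 11 for reserpine at 4 dpf, and 5 to 9 and 1 to 8 for 5-HT against reserpine at 2 and 4 dpf. The correlation of 5-HT and reserpine effects was 0.248 or 0.163 at 2 dpf and -0.0415 or -0.154 at 4 dpf with split controls, where the sign reversed but groups without change gave -0.0984 if replicate numbers share an effect (-0.0879 at 2 dpf). Otherwise it ranged from 0.380 to 0.798 at 2 dpf and from -0.0268, reversed without 4 dpf reserpine replicate 1, to 0.456 at 4 dpf, and that of reserpine effects between days from -0.0495, reversed without 4 dpf reserpine replicate 2, to 0.172. The cause was not tested.

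The labels do not pair the replicates. The data hold a hint that the numbers stand for shared conditions, since deviations from the group mean correlated above 0.1 in 12 of 15 pairs of groups, and at 0.179 or more in the 6 pairs of the same day, and the third principal component (9.12% of the variance) put every replicate 2 array at 19.4 or above and every replicate 1 array at -12.0 or below.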

Other observations

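The tests of light or time of day, of the clock's phase and of the lens list were chosen only after the result was seen, as were the values of stage for each day, and the test of stage between replicates was written before. Circadian genes differed between replicate 1 and replicate 2 in the fit with the replicate number as a block. The light-induced clock repressor genes cry1a (-2.99, SE 0.16, adjusted p = 3.04e-04) and per2 (-2.52, SE 0.25, adjusted p = 0.0116) were lower in replicate 2, as were cry3b (-1.84), cry5 (-1.60), the photolyase-related gene cry-dash (-1.12) and the DNA repair gene ddb2 (-1.38), each in 6 of 6 groups. These genes were chosen after their values were seen. The test called 136 of 58127 features, 95 lower and 41 higher in replicate 2, and 8 of 44 circadian genes passed against 53 of 18363 others, or 20 adjusted over the list alone.

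The replicates did differ in lists that rise with age. At 2 dpf replicate 2 had higher pancreas means by 0.60 to 0.74 and higher enterocyte means by 0.24 to 0.46 in 3 of 3 groups. Photoreceptor means there differed by -0.03 to 0.80 and were higher in replicate 2 in 2 of 3 groups. At 4 dpf the differences were -0.29 to -0.02 for pancreas, -0.07 to 0.06 for enterocyte and -0.26 to -0.05 for photoreceptor means. Against such a difference in stage as the source of the passing features, their replicate difference correlated with the change with age in controls at r = -0.0199 (-0.0128 with the 2 dpf and -0.0256 with the 4 dpf arrays) across features, which are not independent replicates. A shift of the clock's phase alone was not decided. Its test held that the 6 genes of the positive limb would move the other way from per and cry genes. They had a median of -0.229 (from -0.587 to -0.0183) beside -1.03 for 12 per and cry genes, the direction written against such a shift. Without known times of collection, genes of both limbs could fall between the replicates, so the test cannot exclude it. Collection at another time of day or after another light exposure stays open and was not decided: clock genes passed more often than other genes (one-sided Fisher's exact p = 1.46e-12), but this restates the pattern, counts co-regulated genes as independent and cannot speak for a source. The labels give no time of collection, and the study's groups do not part the replicate numbers.

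Lens genes lay lower in 4 dpf reserpine larvae, with a median of -0.59 over 49 members. A single array with less lens RNA may account for part of it, since the median was -0.205 without 4 dpf reserpine replicate 1 (adjusted p = 0.242), whose list mean of 7.13 was the lowest of the 12 arrays. The injection of reserpine stays open: 1 of the 2 dpf reserpine replicates had a list mean above both controls, which was the bound written against it, but the excess of 0.0588 was within the SD of these controls (0.255).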
